A study of Salmo salar with 4 samples.

How the data were processed

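Gene expression was compared between head kidney of Atlantic salmon (Salmo salar) infected with Piscirickettsia salmonis and head kidney of non-infected fish, on 4 two-colour cDNA arrays. Per the labels, kidney of 10 fish was pooled for each condition, about 200 ng of mRNA was the template for RNA amplification, and 2 infected samples were joined to give 8.9 µg of amplified RNA, against 8.4 µg from 1 non-infected sample. Each labelled target was made from 2 µg of that amplified RNA by random-primed reverse transcription with Cy3-dUTP or Cy5-dUTP. The infected pool carried Cy3 on 2 arrays and Cy5 on the other 2. All 4 arrays therefore measured the same pair of RNA pools. They were treated as 1 biological replicate per condition with 4 technical measurements, and no test across fish was made. The array replicate numbers used here are in the order of deposition and pair nothing.

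The authors deposited 1 log2 ratio per spot and array, 8736 spots on each of 4 arrays with no missing value. The scanner, the image analysis, any background correction and the numerator of the ratio are not given in the sources used here. The log base was checked on the values. Raised as powers of 2, 63 of 34944 values were ratios of whole numbers up to 300 and 501 were ratios of whole numbers up to 2000, within 5.5e-10 on the log scale. Powers of e gave 0 and 21, and powers of 10 gave 0 and 29. The deposited values were therefore taken as log2 ratios. Most values matched no such ratio, so this shows the log base and not whether intensities had been rescaled. The medians of the arrays lay between -1.02 and -0.57, so the values had not been centred. Intensities and flags were not used here. Control spots were to be left out, but the tables used here mark none, so all spots were kept. The number of arrays limits the precision.

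The ratio was read as 1 dye over the other on every array. This rests on the 74 spots with a centred ratio of at least 1 in absolute value on all 4 arrays, of which 69 turned sign between the dye orientations and 5 kept it. It assumes that the largest ratios come from the pools and not from the dyes. Over all spots the ranks leaned the other way, with Spearman correlations of 0.09 to 0.22 as deposited between arrays of opposite orientation. Were the ratio infected over non-infected on every array, differences read here as infection would be dye effects, and the reverse. These values do not exclude that. The ratio was taken as Cy5 over Cy3, the customary form of a two-colour ratio and channel 2 over channel 1 in the labels. No source used here states this, so the direction of every difference is called likely. If the ratio were Cy3 over Cy5, each sign would turn and every size and grouping would stay. The side of 0 on which a gene with a small ratio lies also depends on the centring.

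Each array was centred on its median, by a rule for medians more than 0.1 from 0 that was set before the data were examined. The sign of the arrays with infected RNA in Cy3 was turned, the arrays of an orientation were averaged, and the mean of both orientations was taken with equal weight, which cancels a dye effect that is common to the orientations. The error given is the SD between arrays of the same orientation, pooled over both orientations (2 arrays each). The SD over all 4 arrays also contains the dye effect and is given for the leading genes. Centring moved all mean ratios down by 0.20 (log2) against the values as deposited. A spot was called at least 2-fold different when its absolute mean log2 ratio was at least 1 and its sign was the same on all 4 arrays. The same rule was applied to combinations of arrays in which infection cancels. On simulated arrays of 8736 spots with the dye effect and noise of this comparison, the rule called 100% of 100 spots changed by 1.5 (log2) and 2% of 100 spots changed by 0.7, with 1 call among unchanged spots. The simulated noise was only that between arrays of the same orientation. It checks the working of the rule and not false calls from differences between fish or amplifications.

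Genes were named from GEO's annotation of the array platform, which can be outdated and gives 1 symbol for 192 of the 8736 spots (2.2%) and several for none. The other 8544 spots are unnamed here. The named spots hold 94 cDNA clones of 45 genes. Symbols were updated through the Entrez number in a RefSeq table of assembly Ssal_v3.1, which held 42 of the 45 genes, and where the symbol was only a LOC number a synonym from that table is used. The remaining 3 (mt-a, rps7 and a sod1 entry) keep the name of the annotation. Spots of a gene were averaged on each array. No genome build belongs to the values, so no coordinates are given. Salmonid genomes hold many near-identical duplicated genes, and cDNA spots cannot separate their transcripts.

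Also beforehand, 26 gene lists were fixed by keyword, of which 13 had at least 1 named member. Those without one covered acute phase, cytokine, interferon, MHC class II, B cell, T and NK cell, lysosomal protease, respiratory chain, glycolysis, cytoskeleton, proliferation, pancreas and gut, and interrenal genes. The named genes were matched to the keywords by hand. A list was described by the median over its spots, and for lists of 2 or more genes by the percentile of that median among 10000 random draws of as many genes from the 45 named genes, not matched on signal. The percentile describes these 2 pools only. The rule for named genes was also fixed beforehand: up to 15 gene names on each side with a called spot, and for each list up to 2 members farthest to each side among those with 1 sign on all 4 arrays. Other genes were chosen after their values were seen.

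Alternatives fixed beforehand were the values without centring, arrays scaled to equal median absolute deviation, the median of the arrays, each array left out, each orientation alone, other fold rules, genes counted in place of spots, and limma 3.58.1 (R 4.3.3) with an infection and a dye term over the 4 arrays. The limma test measures only error between arrays of the same RNA pools. On simulated arrays of the same 8736 spots at a false discovery rate of 0.05, it recovered 40% of 100 spots changed by 0.5 (log2) and 85% of 100 changed by 1.2, with 3 calls among unchanged spots. Centring by lowess along the dye effect, averaging of neighbouring duplicate spots and a sign rule free of the dye effect were added after seeing the data.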

Results

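The data were 4 two-colour cDNA arrays of Atlantic salmon head kidney, the main blood-forming and lymphoid organ of bony fish. They asked how gene expression in this organ differs between fish infected with Piscirickettsia salmonis, an intracellular bacterium that causes piscirickettsiosis, and non-infected fish. Each array compared 1 infected pool with 1 non-infected pool of 10 fish each. The infected pool was in Cy3 on 2 arrays and in Cy5 on 2 arrays. Each array gave 8736 spots. Signs below take the deposited ratio as Cy5 over Cy3, so that a positive value means likely higher in the infected pool. If the ratio was Cy3 over Cy5, all signs turn together. That it is 1 dye over the other on every array is also an assumption. There was no replicate of either pool, so no difference has a check between fish, and errors are technical.

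Of the 8736 spots, 137 were at least 2-fold likely higher and 92 at least 2-fold likely lower in the infected pool (229 spots, 2.62%). Without centring of the arrays the split was 277 likely higher and 47 likely lower. Neighbouring spots are duplicates of 1 clone wherever they are named, so these counts exceed the number of clones. Neighbouring spots averaged gave 70 likely higher and 45 likely lower of 4368 values. The mean ratio reached 4-fold on 11 spots of the likely higher side and on 8 of the likely lower side. Among the named spots, 10 of the likely higher side belonged to 3 genes, CLC4E, C209E and antithrombin, and 7 of the likely lower side belonged to 4 genes, mt-a, hba, metA and mlc-2. The same rule applied to the 2 combinations of arrays that set arrays of the same orientation against each other called 0 and 0 spots. Applied to the part of the ratio that did not turn with the dyes it called 48, all on 1 side. The infection contrast had an SD over spots of 0.41 (log2), the dye contrast 0.41, and the 2 noise contrasts 0.10 and 0.11. Arrays of the same orientation correlated at Pearson's r = 0.85 and 0.90 across spots. Arrays of opposite orientation correlated between -0.07 and 0.05 as deposited, where infection and dye effects oppose each other. Their Spearman correlations as deposited were all positive, from 0.09 to 0.22. By rank, spots therefore leaned to keeping their ratio between the orientations and not to turning it.

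**Figure D1:**
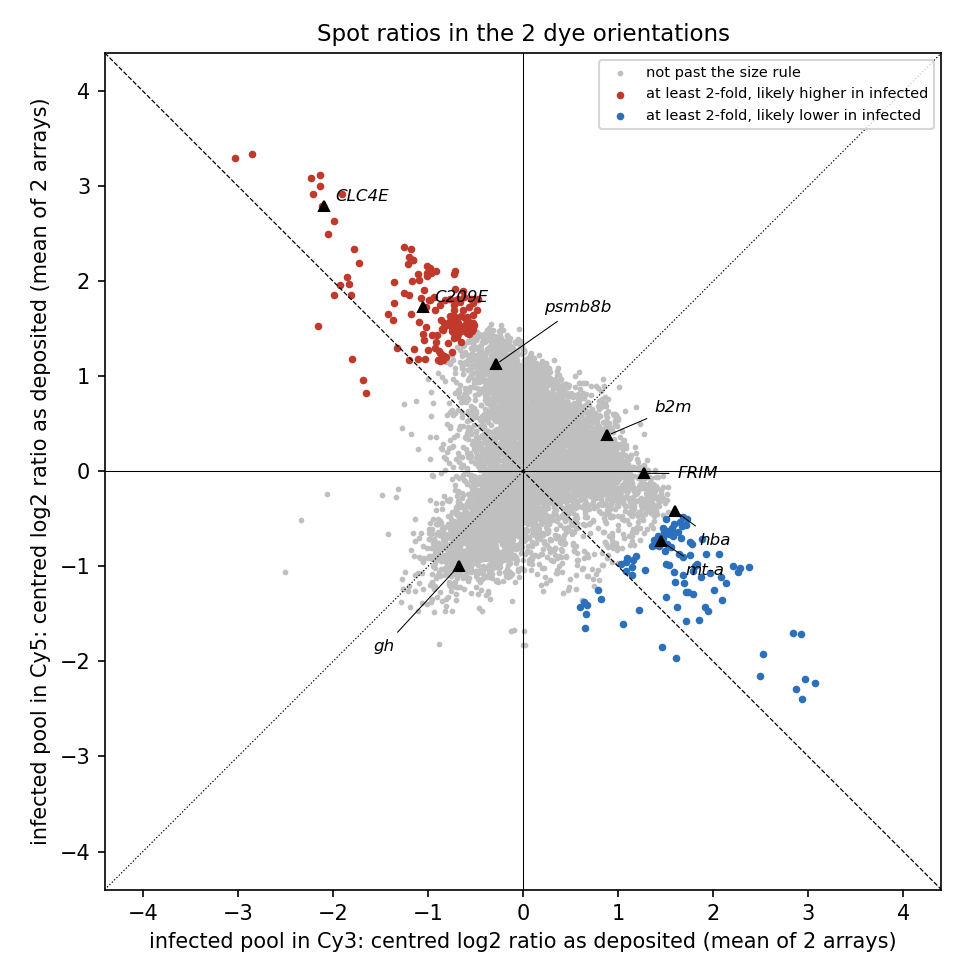
Each point is 1 spot, with its centred deposited log2 ratio averaged over the 2 arrays with the infected pool in Cy3 (x axis) and over the 2 arrays with it in Cy5 (y axis). Differences between the pools lie along the dashed line and dye effects along the dotted line; triangles are means of named genes, red points are the 137 spots at least 2-fold likely higher and blue points the 92 likely lower in the infected pool.

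C-type lectin receptors held the largest differences among the named genes. CLC4E (LOC100136447), whose name stands for C-type lectin domain family 4 member E, a receptor by which myeloid cells sense microbial and damage-associated ligands, was 5.44-fold likely higher in the infected pool. Its mean log2 ratio was 2.44 ± 0.18 (SD within orientation, 2 arrays each; SD over all 4 arrays 0.43). The 2 clones of the gene lay at 2.30 and 2.59, and 4 of its 4 spots passed the size rule. C209E (LOC100136446), named for the CD209 family of lectins of dendritic cells and macrophages, was 2.63-fold likely higher at 1.39 ± 0.18 (SD over 4 arrays 0.42), with 3 clones between 1.07 and 1.57. Of its 6 spots 5 passed the rule. The third member of the granulocyte and macrophage list, mif, a cytokine gene that many cell types express, did not pass and lay at -0.25 ± 0.15. It was positive on 2 of 4 arrays. Of the 3 genes in the list, 2 were at least 2-fold likely higher and 1 was neither. The median over 12 spots was 1.55, at percentile 99.7 of random lists of the named genes. This list rests on lectin genes and holds no other marker of these cells among the named spots. In the same comparison the erythroid genes hba, hbb1 and hbb were at -1.01, -0.76 and -0.25, the last positive on 2 of 4 arrays.

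The inducible proteasome subunits lay on the same side with smaller values. The subunits psmb8b and psmb9a can replace constitutive subunits of the proteasome, a source of peptides for MHC class I. They were at 0.70 ± 0.07 and 0.64 ± 0.08 (1.63-fold and 1.56-fold), positive on 4 of 4 arrays. Their SD over 4 arrays was 0.49 and 0.51. On the Cy3 orientation they were at 0.28 and 0.21, and on the Cy5 orientation at 1.13 and 1.08. The value of psmb9a rests on 1 clone. None of the 5 genes in the MHC class I list passed the 2-fold rule. The peptide transporter gene tap1 was at 0.21 ± 0.05, the tapasin gene tapbp at -0.27 ± 0.28, and b2m, which encodes the light chain of class I molecules, at -0.25 ± 0.08 over 11 clones. Of 4 arrays, tap1 was positive on 3, tapbp on 1 and b2m on 2. The list's median over spots was -0.21, at percentile 24.1, because 24 of its 36 spots are b2m. With the spots of each gene averaged first the median was 0.21. The values of b2m and tapbp without centring were -0.06 and -0.08. The proteasome list consisted of the 2 subunits and had a median of 0.67, at percentile 91.8.

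Among the globin genes, the alpha globin hba was 2.02-fold likely lower, with a mean log2 ratio of -1.01 ± 0.11 (SD over 4 arrays 0.69) and 2 clones at -1.11 and -0.91. The beta globin hbb1 was at -0.76 ± 0.06 (SD over 4 arrays 0.74), negative on 4 of 4 arrays. On the arrays with infected RNA in Cy5 alone hbb1 was at -0.12. The beta globin hbb was at -0.25 ± 0.06, positive on 2 of 4 arrays, and at -0.06 without centring. Of the 3 genes in the erythroid list, 1 was at least 2-fold likely lower and 2 were neither, with a median of -0.76 at percentile 1.03, and of -0.39 without hba. The value of hba sits at the limit. Without centring it was -0.82, on the arrays with infected RNA in Cy5 alone it was -0.42, and leaving out single arrays gave -1.06 to -0.96, past the limit or not depending on the array.

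Metallothioneins, small cysteine-rich proteins that bind zinc and copper, were negative on 4 of 4 arrays. The entry mt-a was 2.14-fold likely lower at -1.10 ± 0.02 (SD over 4 arrays 0.41), and was at -0.90 without centring and at -0.74 on the arrays with infected RNA in Cy5 alone. The entry metA (LOC100136589) averaged -0.94 ± 0.03, and its 2 clones differed, at -1.28 and -0.60. The 2 entries share a gene name in the tables used, and cDNA spots do not separate such near-identical transcripts. In the same antioxidant list, the 2 entries for sod1, the cytosolic superoxide dismutase, were at 0.38 ± 0.07 and 0.23 ± 0.10 and did not pass. Each was positive on 3 of 4 arrays. They were at 0.04 and 0.00 on the Cy3 orientation and at 0.72 and 0.45 on the Cy5 orientation. Of the 4 genes 1 was at least 2-fold likely lower and 3 were neither. The median of the list was -0.60, at percentile 2.86. It was -0.36 with the spots of each gene averaged first and -0.22 without mt-a.

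None of the 3 iron-handling genes passed the rule, and none had the same sign on all 4 arrays. The ferritin heavy subunit gene FRIH (LOC100136564) lay at 0.34 ± 0.02 over 4 clones between 0.14 and 0.51, and at -0.21 on the arrays with infected RNA in Cy3 alone. The middle subunit gene FRIM (LOC100136565) lay at -0.65 ± 0.13 over 3 clones between -0.68 and -0.63, and at -0.02 on the arrays with infected RNA in Cy5 alone. The transferrin gene tfa was at -0.11 ± 0.08 over 7 clones, and at 0.09 without centring. The list's median of -0.05 (0.15 without centring) stood at percentile 58.7.

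Among lists with 1 named gene, antithrombin, an inhibitor of coagulation proteases, was at 0.92 ± 0.07 (1.90-fold, positive on 4 of 4 arrays), and 1 of its 2 spots passed the rule. Without centring its mean was 1.12. The chaperone gene hsp90ab1 was at 0.38 ± 0.05 over 3 clones and mcl-1, an inhibitor of apoptosis, at 0.20 ± 0.10. Both turned sign with the dyes, at -0.11 and -0.28 on the Cy3 orientation and 0.86 and 0.69 on the Cy5 orientation. The translation genes rps7 and EF1A2 (LOC100136525) were at -0.19 ± 0.07 and -0.18 ± 0.07, and without centring at 0.00 and 0.02. Each was positive on 2 of 4 arrays. None of these genes passed the rule as a mean over spots.

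Markers of other tissues were measured beside these groups. Of the skeletal muscle genes, the myosin light chain mlc-2 was at -0.71 ± 0.08, negative on 4 of 4 arrays, with clones at -1.02 and -0.40. The parvalbumin pvalb1 was at -0.29 ± 0.09 over 9 clones and prvb at -0.06 ± 0.08 (0.14 without centring). Both were positive on 2 of 4 arrays. None of the 3 passed the rule as a gene, and the median was -0.33 at percentile 12.5. The liver marker apoa1 was at 0.00 ± 0.08, positive on 2 of 4 arrays.

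**Figure D2:**
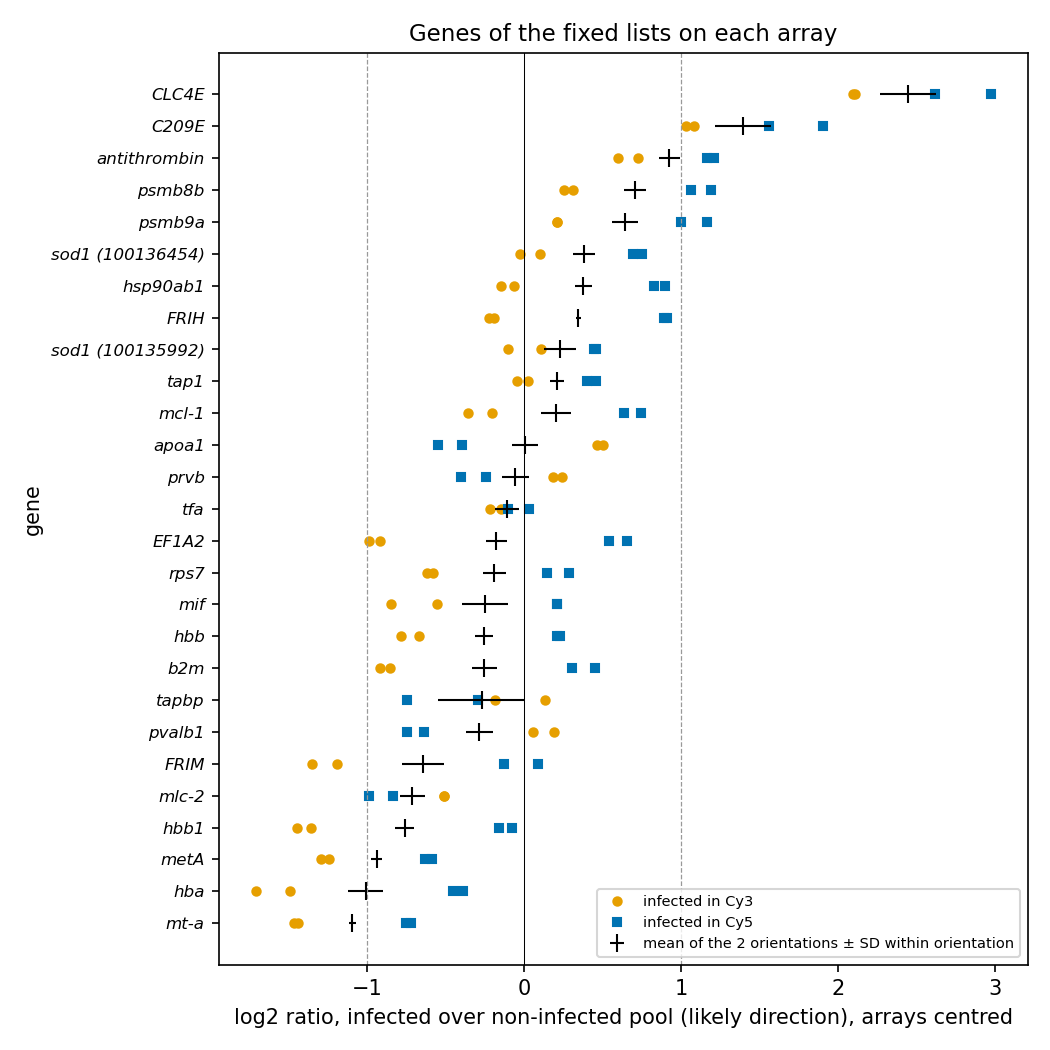
For each of the 27 genes in the fixed lists (rows), the log2 ratio of the infected over the non-infected pool is shown on each array (circles, infected in Cy3; squares, infected in Cy5), with the mean of the orientations and the SD within orientation as a bar. Dashed lines mark 2-fold, and CLC4E and C209E lie beyond it on all 4 arrays, while the orientations of b2m, hbb and FRIH lie on opposite sides of 0.

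Over the 45 named genes as means of their spots, 2 were at least 2-fold likely higher (CLC4E and C209E), 2 at least 2-fold likely lower (mt-a and hba) and 41 neither. The sign was the same on all 4 arrays for 11 genes, 5 positive and 6 negative. Of the 45 genes, 15 changed sign when the arrays were not centred, which moves every mean up by 0.20.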

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

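The form of the ratio (1 dye over the other) and its direction are assumptions that no alternative tests. Without the sign rule the counts were the same 137 likely higher and 92 likely lower spots, so that rule removed none. Counts stayed within 1.5 times under equal array spread, the median of arrays, lowess centring and a sign rule free of the dye effect. Lowess centring, that last rule and averaged neighbouring spots were chosen after seeing the data. Leaving out 1 array gave 127 to 147 likely higher and 92 to 100 likely lower. Without centring there were 277 likely higher and 47 likely lower, since all ratios move up together. The 2 arrays with infected RNA in Cy3 alone gave 97 likely higher and 399 likely lower, and those with it in Cy5 gave 695 likely higher and 237 likely lower, as dye effects no longer cancel. A 1.5-fold rule gave 646 likely higher and 423 likely lower, 2-fold on each array 37 likely higher and 32 likely lower, and 2-fold on at least 3 arrays 63 likely higher and 51 likely lower. Averaged neighbouring spots gave 70 likely higher and 45 likely lower of 4368 values, and gene names 2 and 2. The limma test over arrays called 1776 spots likely higher and 1703 likely lower (Benjamini-Hochberg adjusted p below 0.05), a measure of array error only. On the Cy3 and Cy5 orientations alone, list medians were 0.17 and -0.67 for skeletal muscle, -0.82 and 0.45 for MHC class I and -0.33 and 0.05 for iron, each with a turned sign, -1.40 and -0.12 for erythroid, -0.99 and -0.21 for antioxidant, and 0.23 and 1.13 for proteasome genes. Without centring hba and mt-a were not 2-fold different, nor on the Cy5 orientation alone (-0.42 and -0.74), and hba was not with the median of arrays (-0.97). Iron changed sign without centring (0.15) and without FRIM (0.01), and MHC class I with genes averaged first (0.21). No paired analysis was possible because the array numbers are in order of deposition and all arrays share the same RNA. A rule on missing values was not run because none is missing, nor a filter on dim spots because no intensities are given.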

Other observations

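All tests in this part, and the genes outside the lists, were chosen after the values had been seen. Among named genes outside the lists, ran1, a GTPase of nuclear transport, was at 0.34 ± 0.11 (2 clones at 0.32 and 0.37). The pituitary genes gh and pou1f1 were at -0.16 ± 0.09 and 0.13 ± 0.14, the xenobiotic-response gene cyp1a at -0.10 ± 0.05, and pck2, an enzyme of gluconeogenesis, at 0.00 ± 0.08. Of 4 arrays, ran1 was positive on 3 and gh, pou1f1, cyp1a and pck2 each on 2. Without centring gh was at 0.04, cyp1a at 0.10 and pck2 at 0.19. LOC100136539, which has no other name in the tables used, was at -0.44 ± 0.05 and negative on 4 of 4 arrays. The spots farthest from 0 are unnamed. Spots 1040111 and 1040112, neighbours on the array, were at 3.16 and 3.10 (8.96-fold and 8.55-fold likely higher). On the other side, spot 1020205 was at -2.66 and spot 6010801 at -2.65, and their neighbours were at -2.58 and -2.57. Neighbouring spots are duplicates of 1 clone wherever the annotation names them, and over 4368 neighbours the mean ratios correlated at r = 0.96 across spots.

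CLC4E and C209E lay far on 1 side. Variation between arrays of the same orientation is argued against, since the largest noise contrast among these spots was 0.41 against a smallest infection contrast of 0.99. What stays open is whether infection or any other difference between 1 pool of 10 infected and 1 pool of 10 non-infected fish produced it, including a different mix of cells. The amplification also differed between the pools, with 2 infected samples joined and 1 non-infected sample used. The dye swap cancels no such difference. None of these was tested. In the same list mif was at -0.25, but at -0.70 on the Cy3 orientation and 0.21 on the Cy5 orientation. The erythroid genes hba and hbb1 were at -1.01 and -0.76, negative on 4 of 4 arrays. The third erythroid gene, hbb, was at -0.25, positive on 2 of 4 arrays, and at -0.06 without centring.

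The means of psmb8b and psmb9a lay above 0 and those of b2m and tapbp below, with tap1 of the same list between at 0.21. With the ratio taken as 1 dye over the other, dye bias is argued against as the cause of their difference from b2m. Both subunits lay at least 0.69 above it on every array (SD within orientation 0.03). Were the ratio infected over non-infected on every array, that difference would itself be a dye effect, and the test cannot decide between these forms. Nor does it settle the side of 0 of b2m itself, which is a gene with a small mean. The gene b2m was at -0.89 on the Cy3 orientation, 0.38 on the Cy5 orientation and -0.06 without centring. For tapbp the smallest difference was 0.075, with an SD of 0.35, so dye bias and noise cannot be told apart from a difference there. A flattening of the ratio on very bright spots may hold b2m near 0. Of the 2 genes with a dye effect above that of b2m (0.63), hbb1 departed from 0 by 0.76, but no intensities are given and the dye effect is no measure of brightness. This explanation therefore stays open. An infection effect on the inducible subunits alone stays open and untested.

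The part of the ratio that did not turn with the dyes was as wide over spots as the difference between the pools, and among the named genes it ran from -1.09 for pparg to 0.78 for EF1A2. A candidate explanation is that it follows the brightness of a spot. On 480 spots the ratio was one of whole numbers up to 2000 on at least 1 array, as dim spots could give, and 77.9% of them lay below the median of all spots. Their median was -0.17, against 0.15 for the others. Brightness itself was not measured, since no intensities are given, so the explanation stays open. No biological explanation was tested for this pattern, since it cancels between the orientations if the ratio is 1 dye over the other. Were the ratio infected over non-infected on every array, this part would hold the difference between the pools.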
